A study of Mus musculus with 12 samples.

How the data were processed

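RNA was sequenced from gonadal white adipose tissue, the tissue in the title of the series, of C57BL/6N mice in 4 groups of 3 libraries: Chow, HFD, HFD Vehicle and HFD PCN. Groups and library numbers were taken from the sample labels. Each library has its own number, and the labels do not say in words that each is a separate animal, so p-values measure the spread between these samples. Per the labels, RNA was extracted with a lipid tissue kit and treated with DNase.

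The authors deposited 2 tables, one for HFD with Chow and one for HFD PCN with HFD Vehicle, each with whole-number counts of reads per gene for 6 libraries. Per the submitters' processing notes HISAT2, HTSeq and DESeq2 were used with the genome build GRCm38 (mm10), with no versions or order given there. The same deposited tables give a log2 fold change and its standard error, a p-value with an adjusted p-value, and a mean of scaled counts (baseMean), all by the authors. The mean was recomputed from the counts within a tolerance of 0.5% for all genes with a mean of at least 10. The adjusted p-values deposited by the authors equalled a Benjamini-Hochberg adjustment over all listed genes. The tables list 30327 and 30453 genes, of which 28008 are in both, and genes listed in 1 table only were not analysed in the third comparison. Some of them had high counts. Cfd (83490 counts), Cyp2e1, Adrb3 and Retn were listed in the diet table only, and Hsph1 (72340 counts), Hsp90aa1, Hspa1a and Hspa1b in the PCN table only. The adipocyte list therefore had no Cfd, Adrb3 or Retn with PCN or in the third comparison, and the adipokine list no Cfd or Retn. Rises and falls ranked by size were ranked among the genes of each comparison. No per-sample column was left unmatched. Of 32772 gene IDs, 32760 were in the reference annotation of GRCm38 used here and 32180 (98.23%) had the same start and end, which are given 1-based. Whether counting used the strand is not given in the sources used here, so genes with over 10% of exon bases overlapped by another gene (21 of 233 named) are marked as uncertain where named. The chi-square per degree of freedom was 8.45 to 301 for replicate pairs, 8.43 to 860 for all 66 pairs of the 12 libraries over genes in both tables, and 38.0 to 407 for the pairs of HFD Vehicle 50, so no pair agreed within sampling noise.

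Counts as deposited were tested in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16, with TMM scaling, the default expression filter and Benjamini-Hochberg adjustment at 0.05, each comparison fitted on its own 6 libraries. Values within each comparison were scaled within it. Levels are mean CPM ± SD over 3 libraries, and log2 fold changes come with a standard error (SE). Depth ranged from 11090117 to 27408092 counts per library. For genes with no count in a group the fold is a lower bound against a floor of 3 counts over the group, and for 1 to 3 counts a ratio with a counting interval is given. Such intervals and floors cover counting error only.

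There were 33 gene lists. They covered adipocyte, lipid, sterol, amino acid, mitochondrial and insulin genes, and immune, stromal, vascular and mesothelial cells. Others covered tissues that a dissection could bring along in mice of either sex (intestine, pancreas, epididymis, ovary and uterus, muscle, blood). The rest covered xenobiotic, glucocorticoid, clock, stress, interferon, cell cycle and immediate early genes, and adipokines. The 31 lists with at least 3 tested members were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01. An estimated correlation and fry were run beside it, and adjustment was over the lists of 1 comparison. The genes the text names were chosen by rule: per comparison the 10 largest rises and falls among called genes without overlap between groups and with a mean of at least 1 CPM, without predicted genes; the 5 smallest adjusted p; of each list up to 4 passing members with the smallest p, or 1 or 2 where none passed; and always Nr1i2, Cyp3a11, Lep, Adipoq, Adgre1, Ucp1 and Nr3c1. The lists, the tests, the naming rule and the alternatives not marked as added were set before the data were examined.

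Whether the diet genes moved with PCN was tested with fry and with an exact two-sided permutation test of a score over 6 libraries. Alternatives were DESeq2 1.42.0, limma-voom, size factors of DESeq2 or upper quartile scaling in edgeR, no filter or a filter of 1 CPM in 3 libraries, all 12 libraries in one fit, a fold threshold, an adjusted p of 0.1, the authors' deposited adjusted p, and leaving out each library in turn. Added after seeing the data were thinning of counts, leaving out mitochondrial genes, the diet score as a covariate, and leaving out HFD Vehicle 50 with DESeq2 or limma-voom. The edgeR test was tested on simulated data with the real means, spread and library sizes and 200 changed genes. It recovered 59% of 2-fold and 91% of 4-fold changes among 15991 genes for HFD against Chow (9 false calls among 159). For HFD PCN against HFD Vehicle it recovered 1% and 45% among 16311 genes (0 false among 46), and for HFD Vehicle against HFD 8% and 59% among 16541 genes (4 false among 71). In the real HFD against Chow comparison 9699 genes passed, far more than the 200 changed here, so recovery there may differ from the simulated shares. Of 30 unchanged simulated lists per comparison camera called 0. Simulated genes varied independently, while the estimated correlation within real lists reached 0.99 (cell cycle, HFD Vehicle against HFD). The count of 0 therefore does not give the rate of false calls among the real lists. Body weights, collection times and raw reads were not used here, and a few genes that the naming rule gave are not reported here.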

Results

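Gene counts were analysed for 12 RNA sequencing libraries of C57BL/6N mice, an inbred laboratory strain, in 4 groups of 3. Mice had been put on chow or on a high-fat diet (HFD) at 6 weeks of age for 18 weeks. Chow and HFD mice had no injection stated in the labels, while the HFD Vehicle and HFD PCN groups were obese mice injected intraperitoneally once a day for 4 days. PCN (pregnenolone 16alpha-carbonitrile) is a steroid that activates the mouse pregnane X receptor (PXR, gene Nr1i2), a nuclear receptor that switches on drug-metabolising genes in liver, and was given at 50 mg/kg. Total counts were 13756819, 13404530 and 11702225 in the Chow libraries 8, 17 and 19. They were 27092232, 27408092 and 16646176 in HFD 4, 30 and 38. In HFD Vehicle 23, 50 and 55 they were 24483210, 11090117 and 18550601, and in HFD PCN 5, 11 and 27 they were 26014587, 17907962 and 16778389.

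The title of the series names gonadal white adipose tissue, while the source label of the samples names duodenum. Fabp4, the fatty acid binding protein of adipocytes, lay between 2865 and 7904 CPM (counts scaled to the library total) in all 12 libraries. The intestinal epithelial genes Epcam and Vil1 reached at most 0.292 and 2.84 CPM. The Y-linked gene Ddx3y lay between 110 and 170 CPM, and Xist at or below 0.301 CPM, in all 12 libraries. This is the pattern of male mice. Mitochondrially encoded genes took 7.30% to 29.6% of the counts in the Chow libraries and 2.30% to 3.47% in the HFD, HFD PCN and other HFD Vehicle libraries, against 7.85% in HFD Vehicle 50. Most of this share, and of its difference between libraries, was mitochondrial ribosomal RNA, at 6.05% to 28.7% in Chow, 1.40% to 2.54% in the others and 7.49% in HFD Vehicle 50. The other mitochondrially encoded genes took 0.879% to 1.25% in Chow, 0.680% to 0.950% in the others and 0.354% in HFD Vehicle 50. The share of mitochondrial ribosomal RNA thus separated Chow from HFD, so whatever sets it cannot be told apart from the diet.

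The library HFD Vehicle 50 stood apart from its group. Across genes, which are not independent replicates, its log2 CPM had a mean correlation of 0.961 with the Chow libraries and 0.858 with the HFD libraries. Within groups the correlations across genes were 0.963 to 0.971 for Chow, 0.992 to 0.994 for HFD, 0.970 to 0.979 for HFD PCN and 0.877 to 0.981 for HFD Vehicle. In this library Adgre1, a macrophage surface gene, was at 68.2 CPM, against 936 and 904 CPM in the other HFD Vehicle libraries and 21 to 74.1 CPM in the Chow libraries. Relative to the Chow mean, its mean log2 level was 0.18 for general macrophage genes, 0.69 for genes of lipid-associated macrophages and -0.16 for cell cycle genes. The same 3 lists stood at 2.54, 3.69 and 2.80 in HFD Vehicle 23 and at 2.45, 4.12 and 2.87 in HFD Vehicle 55.

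**Figure D1:**
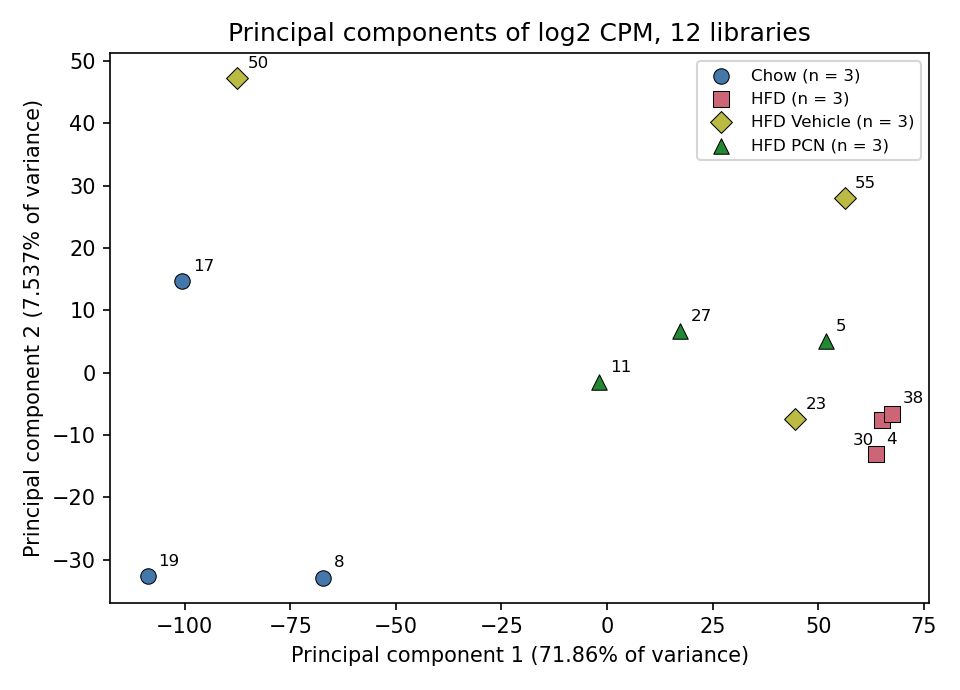
Principal components of log2 CPM over the 12 libraries, each point 1 library with its number, with component 1 (71.86% of the variance) across and component 2 (7.537%) upwards. The library HFD Vehicle 50 lies on the side of the Chow libraries, and the 3 HFD libraries lie close together at the other end.

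The first comparison asked how the high-fat diet changed the tissue. Each library held RNA of the tissue as a whole, and CPM are shares of a library. For all rises and falls below, a change in the mix of cells and a change within a cell type therefore cannot be told apart. Macrophage genes rose in HFD mice: Adgre1 was at 882 ± 24.9 CPM in HFD against 47.4 ± 22.8 CPM in Chow (SD, n = 3 each), an 18.5-fold rise. Spp1, which encodes the secreted protein osteopontin, rose from 1.5 ± 1.14 to 231 ± 23.5 CPM, with 18.8% of its exon bases overlapped by another gene. Adipocyte genes fell: Adipoq, the gene of the hormone adiponectin, fell from 1778 ± 342 to 391 ± 83.4 CPM and Pck1, a gluconeogenic and glyceroneogenic enzyme, from 3347 ± 709 to 144 ± 36.8 CPM. Genes of dividing cells rose, with Mki67 at 179 ± 20.4 CPM in HFD and 27.6 ± 6.55 CPM in Chow. The adipokine gene Lep was at 1298 ± 64.5 CPM in HFD and 1194 ± 656 CPM in Chow and did not pass the test (edgeR adjusted p = 0.775).

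Of 16216 genes tested with edgeR, 9699 passed an adjusted p of 0.05, 4838 higher and 4861 lower in HFD, and 2559 and 2740 of them by at least 2-fold. The libraries of both groups did not overlap in 11104 genes (68.5%), where chance gives 10%. The authors' deposited table held 9599 genes at an adjusted p under 0.05, 5050 higher and 4549 lower. With 1 library left out in turn, edgeR called between 7953 and 10889 genes.

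The smallest adjusted p belonged to Fat3 (ENSMUSG00000074505, an atypical cadherin, GRCm38 chromosome 9, 15910189 to 16501285), at 210 ± 21.8 CPM in HFD and 0.700 ± 0.133 CPM in Chow, a log2 fold change of 8.22 (SE 0.19, edgeR adjusted p = 8.39e-07). Cadm1 (ENSMUSG00000032076, a cell adhesion molecule, chromosome 9, 47530173 to 47857637) rose from 5.6 ± 0.596 to 179 ± 7.69 CPM (log2 fold change 5.00, SE 0.13). Zranb3 (ENSMUSG00000036086, a DNA translocase of replication repair, chromosome 1, 127954184 to 128103047) rose from 5.09 ± 0.216 to 230 ± 29.2 CPM (log2 fold change 5.50, SE 0.15). Syngr1 rose from 1.24 ± 0.287 to 55.7 ± 2.10 CPM, and Galnt6, with 11.4% of its exon bases overlapped by another gene, from 3.49 ± 0.313 to 82.4 ± 5.92 CPM. The chromatin protein gene Hmga2 had 2 counts over the Chow group against 1311 over the HFD group, a ratio of 303 with a counting interval of 83.7 to 2505. The ratio was 227 (interval 40.5 to 8965) for Npy, the neuropeptide Y gene, and 208 (interval 37.1 to 8235) for the serine protease gene Prss46, each with 1 count over the Chow group. Dlgap2, Sstr2, Pou3f1, Rptoros, Olfr1457 and Slc24a5 had no count in Chow and were at least 38.1-fold, 35.3-fold, 34.4-fold, 29.3-fold, 25.6-fold and 31-fold higher in HFD, against a floor of 3 counts over the group. Slc24a5 is uncertain, since 39.5% of its exon bases were overlapped by Myef2.

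The largest fall was that of Cyp2e1 (ENSMUSG00000025479, a cytochrome P450 that oxidises ethanol, chromosome 7, 140763739 to 140774987), from 1251 ± 454 CPM in Chow to 7.12 ± 4.82 CPM in HFD (log2 fold change -7.44, SE 0.57, edgeR adjusted p = 2.64e-05). Cfd (ENSMUSG00000061780, the adipokine adipsin, chromosome 10, 79890853 to 79892655) fell from 2295 ± 1241 to 34.3 ± 12.6 CPM (log2 fold change -6.06, SE 0.53, edgeR adjusted p = 4.62e-05). Adrb3, the beta-3 adrenergic receptor of adipocytes, fell from 597 ± 378 to 8.41 ± 2.79 CPM, with 24.9% of its exon bases overlapped by Gm45470. The other large falls were those of Dnah3 (log2 fold change -6.80), Ripk4 (-5.90), Acsm3 (-5.88), Syt2 (-5.79), Orm3 (-5.67) and Disp2 (-5.49). Dnah3 and Acsm3 are uncertain, with 10.5% and 39.8% of their exon bases overlapped by Lyrm1 and Eri2. Prss55 had 2 counts over the HFD group against 77 over the Chow group, a scaled ratio of 0.0120 with a counting interval of 0.00143 to 0.0449.

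Among genes of adipocyte identity and lipid storage, 19 of 24 tested members fell, 1 rose and 4 did not pass (median log2 fold change -1.84, camera adjusted p = 5.40e-07). With an estimated correlation the list's adjusted p = 0.474. Retn, the adipokine resistin, fell from 427 ± 6.45 to 29.1 ± 8.51 CPM, Acvr1c from 386 ± 77.8 to 66.4 ± 3.36 CPM, and Aqp7, a glycerol channel, from 233 ± 24.9 to 69.6 ± 4.88 CPM. The 1 member that rose, named after its values were seen, was Cd36, a fatty acid transporter also made by macrophages (log2 fold change 0.69). Of 23 adipokines and secreted metabolic factors 12 fell and 3 rose (camera adjusted p = 0.0155, and adjusted p = 0.619 with an estimated correlation). Agt, the angiotensinogen gene, fell from 135 ± 14.1 to 14.2 ± 1.58 CPM, Rbp4 from 215 ± 42.5 to 24.5 ± 1.64 CPM and Vegfa, an angiogenic growth factor, from 324 ± 73.2 to 38.7 ± 5.16 CPM. Of 21 genes of branched-chain amino acid breakdown 19 fell and none rose (median -0.95, camera adjusted p = 2.22e-06, and adjusted p = 0.550 with an estimated correlation), with Ivd falling from 194 ± 31.6 to 43.3 ± 4.59 CPM and Mccc1 from 90.6 ± 8.14 to 35.8 ± 1.77 CPM. Adjusted over the list alone, the counts of the 3 lists were the same.

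In the list of insulin signalling and glucose uptake, 13 of 22 members fell and 4 rose, or 13 and 5 adjusted over the list alone (camera adjusted p = 0.0338, and adjusted p = 0.744 with an estimated correlation). Foxo1 fell from 157 ± 9.40 to 32.1 ± 2.90 CPM and Irs2, an insulin receptor substrate, from 200 ± 26.4 to 40.5 ± 3.40 CPM. Ptpn1, a phosphatase that acts on the insulin receptor, rose from 44.1 ± 1.17 to 111 ± 6.89 CPM. In cholesterol biosynthesis and uptake 16 of 23 members rose and 1 fell, and the same numbers did so adjusted over the list alone (median 1.05, camera adjusted p = 2.17e-04, and adjusted p = 0.619 with an estimated correlation). Sqle, an enzyme of sterol synthesis, rose from 4.39 ± 0.612 to 25 ± 4.36 CPM and Msmo1 from 11.6 ± 1.20 to 57.5 ± 8.77 CPM. Among nuclear-encoded genes of oxidative phosphorylation 21 of 48 rose and 2 fell, or 19 and 2 adjusted over the list alone (median 0.27, camera adjusted p = 0.0138, and adjusted p = 0.755 with an estimated correlation). Cox7b and Ndufs8 rose by 1.14 and 1.03 on the log2 scale.

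Of 20 genes of lipid-associated macrophages 18 rose and 2 did not pass (median log2 fold change 4.47, camera adjusted p = 1.14e-07, and adjusted p = 0.619 with an estimated correlation). Ctsk, a lysosomal protease, rose from 16.1 ± 7.13 to 571 ± 58.0 CPM and Lipa, the lysosomal acid lipase, from 93.2 ± 31.9 to 1276 ± 70.2 CPM. Of 19 general macrophage genes 16 rose and 1 fell, or 16 and 2 adjusted over the list alone (median 2.84, camera adjusted p = 1.73e-05, and adjusted p = 0.619 with an estimated correlation). Ms4a7 rose from 9.80 ± 2.36 to 125 ± 1.19 CPM. Among 24 inflammatory cytokines and chemokines 16 rose and 2 fell (median 1.71, camera adjusted p = 0.00157, and adjusted p = 0.550 with an estimated correlation), with Il1rn, the antagonist of the interleukin-1 receptor, at 120 ± 21.6 against 1.54 ± 0.994 CPM and Ccl2, a monocyte-attracting chemokine, at 27.6 ± 3.75 against 2.01 ± 0.120 CPM. Of 12 neutrophil and mast cell genes 7 rose and 1 fell (median 3.40, camera adjusted p = 0.0105, and adjusted p = 0.744 with an estimated correlation). The members with the smallest p were mast cell genes: Cpa3 rose from 0.846 ± 0.676 to 63.0 ± 9.59 CPM and Cma1 from 0.898 ± 0.792 to 61.4 ± 10.5 CPM. For the lists with no second count given, the counts adjusted over the list alone were the same.

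All 26 cell cycle genes rose (median log2 fold change 2.74, camera adjusted p = 9.92e-11, and adjusted p = 0.550 with an estimated correlation). Pcna, the sliding clamp of DNA replication, rose from 19.8 ± 2.76 to 140 ± 6.16 CPM. Of 28 genes of the extracellular matrix and fibrosis 17 rose and 1 fell (median 1.19, camera adjusted p = 0.00246, and adjusted p = 0.755 with an estimated correlation), with Timp1, an inhibitor of matrix proteases, at 42.5 ± 1.46 against 1.32 ± 0.306 CPM and the protease gene Mmp2 at 251 ± 31.7 against 35.2 ± 7.89 CPM. Of 16 endothelial genes 15 fell and 1 did not pass (median -1.56, camera adjusted p = 1.39e-06, and adjusted p = 0.225 with an estimated correlation). Flt1 and Kdr, both receptors of vascular endothelial growth factor, fell from 275 ± 20.7 to 57.3 ± 2.33 CPM and from 198 ± 11.5 to 39.5 ± 4.63 CPM. Adjusted over the list alone, the counts of the 3 lists were the same.

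Of 17 tested genes of PXR and CAR targets and xenobiotic metabolism 9 fell and 1 rose (median log2 fold change -0.49, camera adjusted p = 0.0155, and adjusted p = 0.550 with an estimated correlation). Abcb1a, a drug efflux pump with 10.1% of its exon bases overlapped by another gene, fell from 41.1 ± 4.13 to 13.3 ± 1.13 CPM, and Gsta4, a glutathione transferase, from 8.09 ± 1.32 to 0.879 ± 0.393 CPM. Nr1i2 itself had counts of 0, 0 and 1 in HFD 4, 30 and 38 and the same in Chow 8, 17 and 19. These counts lay at or under the floor of 3 counts, so no fold is given. Among glucocorticoid receptor targets 10 of 22 fell and 1 rose (median -0.69, camera adjusted p = 0.0465, and adjusted p = 0.755 with an estimated correlation), with Zbtb16 falling from 680 ± 201 to 118 ± 5.05 CPM, while the receptor gene Nr3c1 was at 172 ± 8.19 CPM in HFD and 204 ± 29.0 CPM in Chow and did not pass (edgeR adjusted p = 0.127). Of 18 circadian clock genes 10 fell and 1 rose (median -0.98, camera adjusted p = 0.0338, and adjusted p = 0.711 with an estimated correlation), with Nr1d1, a repressor of the clock, falling from 103 ± 41.4 to 17.0 ± 3.81 CPM. For the clock genes, an effect of the diet and another time of day at tissue collection cannot be told apart, since collection times were not used here. Adjusted over the list alone, the counts of the 3 lists were the same.

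Of 31 lists tested in this comparison 16 passed camera with the preset correlation, 0 with an estimated correlation, and 19 passed fry, which tests whether a list's genes move one way and does not compare it with other genes. The smallest adjusted p with an estimated correlation was the 0.225 of the endothelial list.

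**Figure D2:**
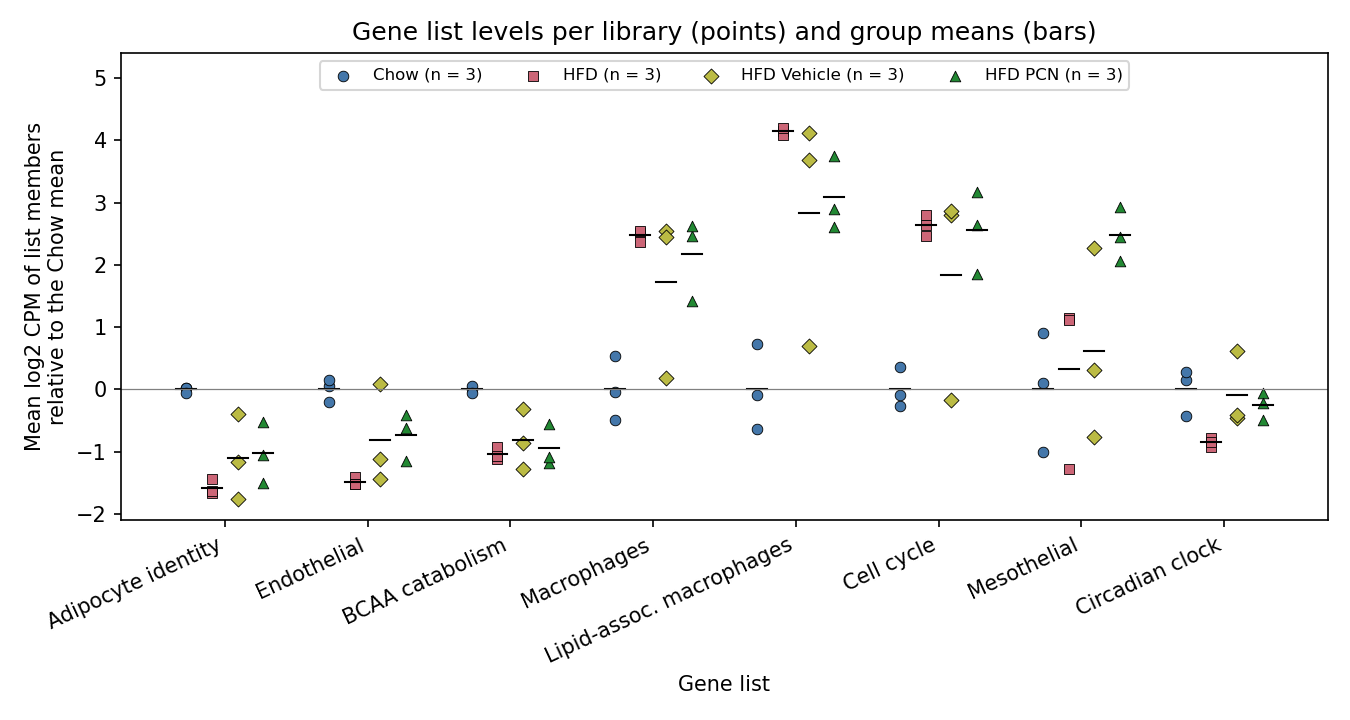
Mean log2 CPM of the members of 8 gene lists relative to the Chow mean, with points for the 12 libraries and bars for the means of the 4 groups (n = 3 each). In HFD Vehicle 50 the 3 lists of general macrophages, lipid-associated macrophages and cell cycle lie at 0.18, 0.69 and -0.16, near the Chow libraries, and the other HFD Vehicle libraries lie between 2.45 and 4.12.

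The second comparison asked what PCN changed in obese mice against its vehicle. The gene with the smallest p was Slpi (ENSMUSG00000017002, a secreted protease inhibitor of epithelia, GRCm38 chromosome 2, 164354070 to 164389095), at 9.71 ± 1.67 CPM with PCN and 1.97 ± 0.930 CPM with vehicle (SD, n = 3 each; log2 fold change 2.33, SE 0.38). In the untreated HFD libraries 4, 30 and 38 Slpi was at 24.2, 8.87 and 1.14 CPM, there without scaling between libraries. Adgrd1 (ENSMUSG00000044017, an adhesion receptor, chromosome 5, 129096750 to 129204599) was at 84.0 ± 10.2 and 45.7 ± 0.979 CPM (log2 fold change 0.88, SE 0.15). The predicted gene Gm25835 was at 20.8 ± 2.40 and 40.3 ± 7.40 CPM, and Tnfrsf11b (ENSMUSG00000063727, the decoy receptor osteoprotegerin, chromosome 15, 54250619 to 54278484) at 6.33 ± 2.53 and 1.65 ± 0.580 CPM. The PXR gene Nr1i2 had counts of 1, 1 and 0 in HFD PCN 5, 11 and 27 and of 5, 0 and 1 in HFD Vehicle 23, 50 and 55. Cyp3a11, the cytochrome P450 gene that PCN induces in liver, had counts of 13, 9 and 0 against 0, 1 and 0.

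With edgeR 0 of 16563 genes passed, with the smallest adjusted p at 0.99986, and 281 genes had an unadjusted p under 0.05, where 828 would be expected by chance. DESeq2 called 1 gene, Slpi (log2 fold change 2.34, DESeq2 adjusted p = 1.45e-04), and limma-voom 0. The authors' deposited table held 2 genes at an adjusted p under 0.05, Slpi (adjusted p = 1.02e-04) and Adgrd1 (0.0456). The libraries did not overlap in 1014 genes (6.12%), where chance gives 10%. Without HFD Vehicle 50, a setting of which the edgeR part was planned and the rest chosen after seeing the data, edgeR called 0 genes (898 at an unadjusted p under 0.05), limma-voom 0 and DESeq2 44, 41 of them higher with PCN. Of the 41, 9 were members of the list of mesothelial markers, which was uneven between libraries, and 1 of that of progenitors. Over the alternatives the smallest adjusted p lay between 4.16e-12, with DESeq2 without that library, and 1. In simulated data with the spread of these libraries edgeR recovered 1% of genes changed 2-fold and 45% of genes changed 4-fold, so most changes of these sizes went uncalled there. Simulated genes varied independently, while whole lists shifted together in HFD Vehicle 50, so the shares for the real data may differ.

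Of the 40 genes of PXR and CAR targets and xenobiotic metabolism 16 had enough counts to be tested. None of the 16 passed, over all genes or adjusted over the list alone, and their median log2 fold change was -0.00, the mean 0.06 and the camera direction up (camera adjusted p = 0.830). Gstm1, a glutathione transferase, was at 282 ± 115 CPM with PCN and 176 ± 23.8 CPM with vehicle, and Aldh1a7 at 23.7 ± 8.83 and 40.6 ± 8.37 CPM. Among the genes not tested, and so outside the median, were Cyp3a11 and others named after their values were seen, with counts over the PCN and the vehicle group. These were Cyp2b10 (17 and 28), Cyp2c29 (11 and 0), Nr1i3 (11 and 2), Slco1a4 (5 and 6), Cyp3a25 (5 and 0), Cyp2c55 (4 and 9) and Cyp3a13 (3 and 7). Adgre1 was at 604 ± 262 and 642 ± 494 CPM, Adipoq at 940 ± 535 and 750 ± 434 CPM, Lep at 1720 ± 582 and 1240 ± 233 CPM, and Nr3c1 at 207 ± 12.4 and 195 ± 6.23 CPM. The thermogenic gene Ucp1 had counts of 11, 2 and 0 against 13, 5 and 3. Fasn, the fatty acid synthase gene, was at 366 ± 177 and 912 ± 518 CPM.

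Mesothelial genes, the markers of the cell layer that covers visceral fat, were the list with the largest median, 1.49 on the log2 scale higher with PCN over 15 members (camera adjusted p = 1.61e-13, and adjusted p = 0.965 with an estimated correlation). Slpi was the 1 member that passed adjusted over the list alone, and 0 passed over all genes. Krt8, a keratin, was at 4.22 ± 1.31 against 0.925 ± 0.764 CPM. The mesothelial list was also uneven within groups, with its mean log2 level spread over 2.43 among the 3 untreated HFD libraries. Progenitor genes had a median of 0.28 (camera adjusted p = 0.00481, and adjusted p = 0.617 with an estimated correlation), with Sfrp4 at 9.56 ± 0.803 against 5.15 ± 0.559 CPM and Cd34 at 106 ± 18.7 against 64.9 ± 13.6 CPM. Relative to the Chow mean, the mean log2 level of the progenitor list was 0.29 to 0.59 with PCN and 0.05 to 0.12 with vehicle. In the untreated HFD libraries it was 0.40 to 0.64, so the vehicle group was the low one. The lists of cell cycle (median 0.31), unfolded protein and integrated stress response (0.26), adipokines (0.22), neutrophils and mast cells (0.04) and cytokines (0.22) passed camera at adjusted p = 0.00481, 0.00599, 0.0148, 0.0409 and 0.0460, and each had an adjusted p = 0.965 with an estimated correlation. No list passed fry (smallest adjusted p = 0.380). The lipid-associated macrophage list had a median of -0.15 and a mean of -0.20 while the camera direction was up (adjusted p = 0.851).

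The list results changed with the library left out. Without HFD Vehicle 50, in which macrophage and cell cycle genes stood near the Chow level, 9 lists passed camera with the preset correlation, and 3 of the 7 (mesothelial cells, progenitors and adipokines) were kept. Without HFD Vehicle 23, 5 lists passed and 3 of the 7 were kept, and without HFD Vehicle 55 these numbers were 13 and 6. They were 4 and 4 without HFD PCN 5, 11 and 6 without HFD PCN 11, and 3 and 3 without HFD PCN 27. No estimated correlation was run with a library left out. On the scale camera uses, mean log2 CPM, the median difference of lipid-associated macrophage genes was 0.30 with all libraries and -0.76 without HFD Vehicle 50 (camera adjusted p = 8.17e-08). For general macrophages it was 0.40 and -0.54 (0.0357), and for cell cycle genes 0.70 and -0.29 (0.0127). Endothelial genes were then 0.50 higher with PCN (4.83e-06), adipocyte genes 0.48 higher (0.00598) and oxidative phosphorylation genes had a median difference of -0.17 (4.83e-06).

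**Figure D3:**
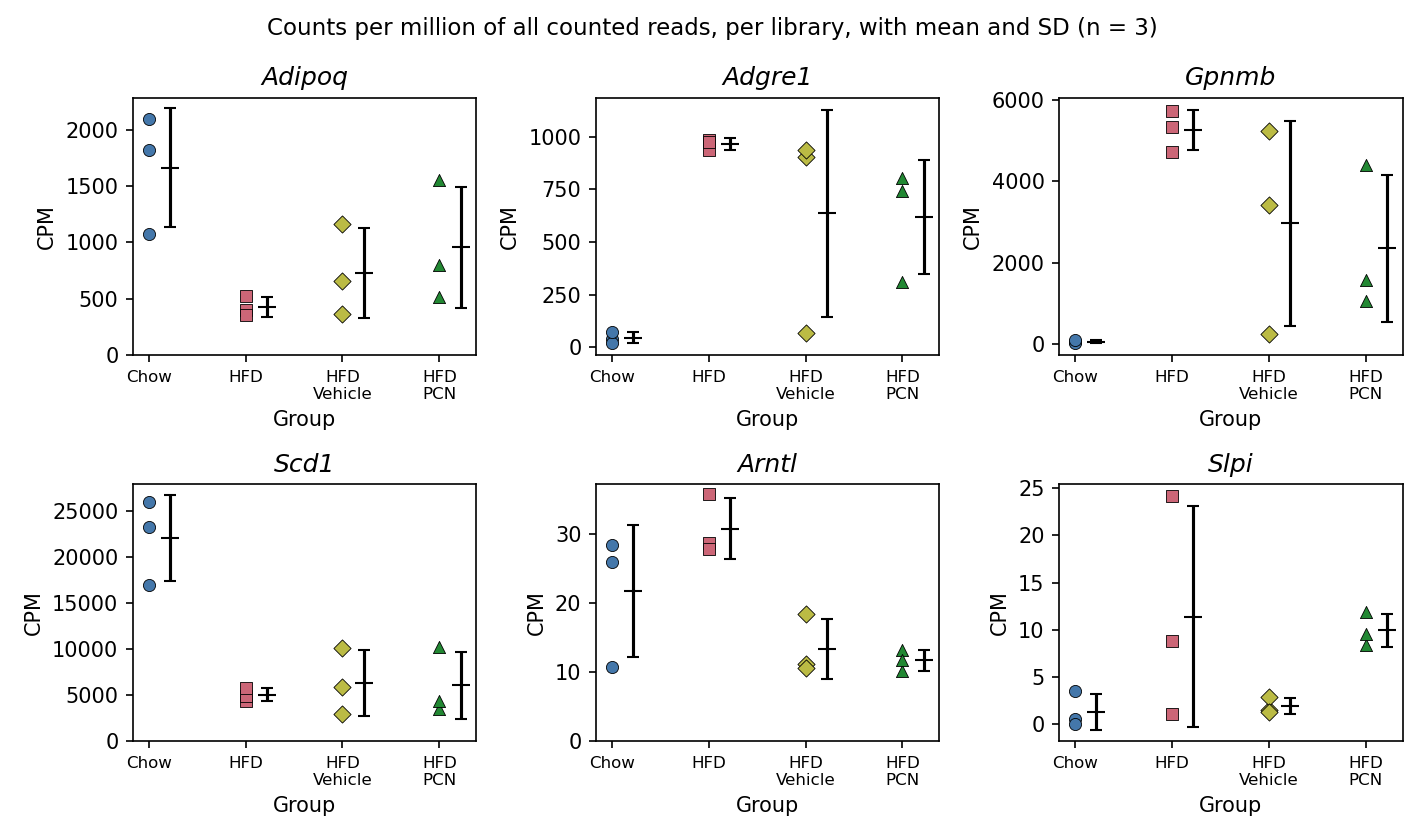
Levels in CPM, without scaling between libraries, of Adipoq, Adgre1, Gpnmb, Scd1, Arntl and Slpi in each of the 12 libraries, with points for libraries and lines for the group mean and SD (n = 3 each). For Adgre1 the library HFD Vehicle 50 lies at 68.2 CPM and the other HFD Vehicle libraries at 936 and 904 CPM; Gpnmb was chosen for plotting after its values were seen.

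The third comparison set HFD Vehicle against HFD as the background of injection and vehicle, and of anything else that separated both sets of mice. Among the clock genes, Arntl, the core activator of the clock, was at 13.4 ± 3.86 CPM in HFD Vehicle and 30.7 ± 4.67 CPM in HFD (SD, n = 3 each), and Dbp, one of its targets with 18.0% of exon bases overlapped by Sphk2, at 52.0 ± 22.7 and 17.0 ± 4.24 CPM. No clock gene passed over all genes, and adjusted over the list alone 11 rose and 2 fell (median log2 fold change 1.10, camera adjusted p = 8.54e-04, and adjusted p = 0.691 with an estimated correlation). In cholesterol biosynthesis and uptake 8 genes fell and 0 rose adjusted over the list alone (median -0.63, camera adjusted p = 2.63e-09, and adjusted p = 0.499 with an estimated correlation). Lss, lanosterol synthase, was at 30.3 ± 4.19 against 55.7 ± 5.03 CPM. No cholesterol gene passed over all genes.

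The smallest p belonged to Mgam, a maltase gene, at 0.939 ± 0.242 CPM in HFD Vehicle and 6.00 ± 0.810 CPM in HFD (log2 fold change -2.64, SE 0.28, edgeR adjusted p = 0.485). Aspn, a matrix proteoglycan, was at 33.8 ± 2.18 and 67.4 ± 3.95 CPM, Gclm, a subunit of the enzyme that starts glutathione synthesis, at 24.8 ± 4.83 and 66.1 ± 8.08 CPM, Wnt2, a secreted signalling protein, at 0.307 ± 0.0452 and 1.57 ± 0.358 CPM, and Cd34 at 64.5 ± 12.6 and 146 ± 13.2 CPM. With edgeR 0 of 16781 genes passed (smallest adjusted p = 0.485), 1639 had an unadjusted p under 0.05 where 839 would be expected, and the libraries did not overlap in 4704 genes (28.0%, where chance gives 10%). DESeq2 called 91 genes, 48 higher and 43 lower, and limma-voom 0. Without HFD Vehicle 50, edgeR called 172 genes, 100 higher and 72 lower (smallest adjusted p = 0.0130), limma-voom 158, again added after seeing the data, and DESeq2 708. Mgam, Aspn and Gclm then passed with log2 fold changes of -2.50, -1.01 and -1.26, each at an edgeR adjusted p = 0.0130, while over the edgeR alternatives the smallest adjusted p lay between 0.0130 and 0.797.

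Lists of macrophages, adipocytes and endothelium also passed camera. Lipid-associated macrophages had a median of -0.71 (camera adjusted p = 4.87e-04), general macrophages -0.45 (0.0329), endothelial cells 0.68 (4.87e-04) and adipocyte identity 0.64 (0.0278), with estimated-correlation adjusted p from 0.483 to 0.760 over all the lists that passed here. In HFD Vehicle 50 the endothelial and adipocyte lists stood at 0.09 and -0.39 relative to the Chow mean, against -1.11 and -1.17 in HFD Vehicle 23 and -1.43 and -1.76 in HFD Vehicle 55. Adgre1 was at 634 ± 486 CPM against 960 ± 26.2 CPM, the HFD level differing from that given against Chow since values were scaled within each comparison. The other lists that passed camera were oxidative phosphorylation (median -0.30, adjusted p = 1.59e-06), neutrophils and mast cells (-1.77, 2.34e-04), extracellular matrix (-0.44, 2.34e-04), T and NK cells (-0.74, 4.87e-04), progenitors (-0.52, 0.00188), cell cycle (-0.30, 0.00734), de novo lipogenesis (-0.32, 0.0158) and dendritic cells (-0.28, 0.0206). Scd2, a lipogenic desaturase, was at 106 ± 13.9 against 208 ± 14.5 CPM. No list passed fry in this comparison (smallest adjusted p = 0.0855). Without HFD Vehicle 50, 13 lists passed camera and 11 of the 14 were kept, the clock and cholesterol lists among them, while the adipocyte (adjusted p = 0.374) and general macrophage (0.981) lists did not pass and the cell cycle list turned to 0.19 (6.35e-04). On the scale of mean log2 CPM, the median difference of lipid-associated macrophages was -1.44 with all libraries and -0.18 without that library (camera adjusted p = 0.00456). That of endothelial cells was 0.59 and 0.24 (0.00679), so both lists still passed in the same direction with smaller medians.

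Whether genes that the diet moved also moved with PCN was tested on 15915 genes measured in both tables, 4793 called higher and 4688 called lower in HFD against Chow. The score, the mean standardised level of the first set minus that of the second, was 0.17 ± 0.85 with PCN and -0.17 ± 2.29 with vehicle (SD, n = 3 each). The difference of 0.34 had an exact two-sided permutation p = 0.9, where 0.1 is the smallest that 3 against 3 allows, and a fry p = 0.82. HFD Vehicle 23, 50 and 55 scored 0.883, -2.79 and 1.40, and HFD PCN 5, 11 and 27 scored 1.12, -0.526 and -0.0851. Without HFD Vehicle 50 the difference was -1.36, and without HFD PCN 5 it was -0.12, so its direction turned when either library was left out. Across genes, which are not independent replicates, the Spearman correlation of both sets of log2 fold changes was 0.251. Overlap of calls was 0, since edgeR called 0 genes with PCN.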

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

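The settings without HFD Vehicle 50 under DESeq2 or limma-voom, thinning, the removal of mitochondrial genes and the score covariate were chosen after seeing the data, and the others were planned. Of the alternatives of the main values 153 stayed the same, 22 moved and 2 reversed, and of those of named genes and lists 2717 stayed the same, 62 became stronger, 106 weaker and 19 reversed. The HFD against Chow count of 9699 stayed within 1.5 times under every setting except the fold threshold, which by construction left 5299 genes, 2559 higher and 2740 lower, and no called gene changed sign under any setting. Leaving out 1 library gave 7953 to 10889 genes, 4107 to 5491 higher and 3846 to 5398 lower. Upper quartile scaling gave 44% of calls higher and shifted the median of all genes by -0.096 on the log2 scale. No paired analysis was possible because the groups share no replicate numbers.

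For HFD PCN against HFD Vehicle, edgeR gave 0 genes without any 1 library. The count was 1 with DESeq2, 1 higher, 2 by the authors' deposited adjusted p, 2 higher, and 44 with DESeq2 without HFD Vehicle 50, 41 higher and 3 lower. For HFD Vehicle against HFD, DESeq2 gave 91 genes, 48 higher and 43 lower. Leaving out 1 library gave 0 to 172 with edgeR, 0 to 100 higher and 0 to 72 lower, the highest without HFD Vehicle 50. Without that library DESeq2 gave 708 genes, 397 higher and 311 lower, and limma-voom 158, 92 higher and 66 lower. The cause was not tested beyond leaving out that library. The diet score difference lay between -1.36 and 1.09 with 1 library left out, and reversed from 0.34 to -1.36 without HFD Vehicle 50 and to -0.12 without HFD PCN 5.

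With 1 library left out, the log2 fold change of Lep in HFD against Chow lay between -0.10 (without Chow 19) and 0.69 (without Chow 8), and was -0.064 without Chow 17. With PCN the ranges were -1.07 to 0.044 for Prdm16, -1.40 to 0.029 for Ovgp1 and -0.012 to 0.88 for Aurkb, each turning without HFD Vehicle 50. They were -1.19 to 0.048 for Itgax and -0.72 to 0.16 for Anpep, each turning without HFD Vehicle 55. Adgre1 lay between -0.62 and 0.28, turning without HFD Vehicle 23, without HFD Vehicle 55 (0.27) and without HFD PCN 11 (0.23). Adipoq lay between -0.22 (without HFD PCN 11) and 0.87, and was -0.017 without HFD Vehicle 55. Krt7 in HFD Vehicle against HFD lay between -0.13 (without HFD Vehicle 50) and 2.63. None of these genes had passed the test.

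With 1 library left out, camera passed 13 to 16 lists in HFD against Chow, 3 to 13 with PCN and 11 to 17 in HFD Vehicle against HFD. For 5 lists the camera direction with PCN turned without HFD Vehicle 50, counting only lists that passed with all libraries or without that library. Of these, cell cycle passed in both settings, cytokines and neutrophils and mast cells with all libraries alone, and both macrophage lists without that library alone. Their medians, as differences of mean log2 CPM, had ranges of -0.54 to 0.91 for general macrophages, -0.76 to 1.02 for lipid-associated macrophages, -0.058 to 0.56 for cytokines, -0.22 to 0.88 for neutrophils and mast cells and -0.29 to 1.21 for cell cycle. In HFD Vehicle against HFD the cell cycle list lay between -1.39 and 0.19, turning without the same library. Medians of further lists changed sign without it too, such as adipocyte identity with PCN (from -0.0018 to 0.48) and mesothelial cells in HFD Vehicle against HFD (from 0.37 to -0.53). Nr1i2 had at most 5 counts and Cyp3a11 at most 13 in any library, where totals were 11090117 to 27408092. Both genes were thus barely detected at these depths, and neither was tested with PCN.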

Other observations

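The tests of the 3 patterns weighed here were chosen after the results were seen, while the gene lists and the counts over other splits of the libraries were set before. Further lists of HFD against Chow held members that passed in both directions. Of 22 genes of the unfolded protein and integrated stress response 13 rose and 4 fell (camera adjusted p = 0.157), with Atf3, a stress-induced transcription factor, at 301 ± 25.8 CPM in HFD against 9.96 ± 6.13 CPM in Chow (SD, n = 3 each) and Sesn2 and Chac1 falling by 1.93 and 2.07 on the log2 scale. Of 20 immediate early genes 6 rose and 6 fell (median log2 fold change -0.25, mean 0.21, camera direction down, adjusted p = 0.942), with Egr2 at 32.0 ± 1.89 against 2.48 ± 0.324 CPM and Nr4a2 at 0.681 ± 0.127 against 3.12 ± 0.429 CPM. Of 24 interferon-stimulated genes 7 rose and 3 fell, or 4 and 2 adjusted over the list alone (camera adjusted p = 0.416), with Oas1a rising from 2.49 ± 0.488 to 13.6 ± 1.09 CPM. Of 14 thermogenic genes 6 rose and 3 fell (median 0.04, mean 0.88, camera adjusted p = 0.379). Dio2, which activates thyroid hormone, rose from 0.150 ± 0.0757 to 3.05 ± 0.979 CPM and Ebf2 fell from 51.5 ± 12.8 to 15.5 ± 1.76 CPM. Ucp1 counts were 8, 3 and 10 in HFD 4, 30 and 38 and 0, 3 and 1 in Chow 8, 17 and 19. De novo lipogenesis had 6 rises and 8 falls among 20 (camera adjusted p = 0.412), with Scd1, a desaturase, falling from 23747 ± 1699 to 4599 ± 690 CPM. Fatty acid beta-oxidation had 3 rises and 7 falls among 20 (camera adjusted p = 0.218), with Cpt1a, the carnitine transferase of mitochondria, rising from 99.4 ± 21.6 to 284 ± 5.49 CPM and Ppara falling from 13.9 ± 2.25 to 3.21 ± 0.580 CPM. Where no second count is given, it was the same adjusted over the list alone.

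Among other cell types, 3 of 19 T and NK cell genes rose and 16 did not pass (camera adjusted p = 0.0995), with Il7r at 149 ± 8.84 CPM in HFD against 10.4 ± 4.30 CPM in Chow. Of 10 B and plasma cell genes 4 rose (camera adjusted p = 0.242), with Cd22 at 16.5 ± 1.79 against 1.49 ± 0.549 CPM. Of 14 dendritic cell genes 3 rose and 3 fell (camera adjusted p = 0.487), and of 17 progenitor genes 9 rose and 2 fell (camera adjusted p = 0.157), with Pdgfra rising from 96.4 ± 22.8 to 206 ± 18.1 CPM. No mesothelial gene of 13 passed (camera adjusted p = 0.846). Of the lists for neighbouring tissues, 6 of 24 intestinal genes could be tested, 2 rose and 4 fell (camera adjusted p = 0.434). Of 7 skeletal muscle genes 3 rose and 3 fell (camera adjusted p = 0.837). Of 7 ovary and uterus genes, tested since the list was set beforehand although the libraries looked male, 2 rose and 3 fell (median 0.17, mean -0.31, camera direction up, adjusted p = 0.955). Of 8 red blood cell genes 2 fell, or 0 adjusted over the list alone (camera adjusted p = 0.169). For exocrine pancreas 1 gene of 12 could be tested (Cela1, 17.3 ± 2.67 against 10.3 ± 8.16 CPM, not passed), and of 16 epididymis genes 0 could be. Except for the red blood cells, the counts adjusted over the list alone were the same.

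The library HFD Vehicle 50 lay at 0.0729 on an axis from the Chow mean (0) to the HFD mean (1), where the other injected libraries lay at 0.566 to 0.930. With all libraries thinned to the smallest total it stayed 0.489 below the nearest other high-fat-diet library, beyond the range of 0.0336 among the HFD libraries, which argues against depth. A swap with a Chow library needs a Chow library near HFD, and the highest Chow library lay at 0.218. The genes of this axis had been called with the same Chow libraries, so these places lend no support by themselves. Across 15895 genes not chosen by the diet, each Chow library had a mean correlation of 0.965 to 0.969 with the other Chow libraries. With the HFD libraries it was 0.833 to 0.894. The RNA of an uninjected chow-fed mouse under this label may still be the source and cannot be told apart from a mouse that responded little to the diet. On an axis from uninjected (0) to injected (1) the library lay at 0.434. The Chow libraries lay at 0.0192 to 0.228, the HFD libraries at -0.0135 to 0.318 and the other injected ones at 0.550 to 1.14. Of these, HFD Vehicle 23 and 55 lay at 0.558 and 0.655. The injection axis cannot decide, since its injected set joined HFD PCN with HFD Vehicle libraries. No other injected library lay near the place of HFD Vehicle 50 on the diet axis either. For HFD 4 and HFD 38 the axis rested on 100 genes of which 0 and 3 passed. No biological explanation was tested, and body weights were not used here. The share of mitochondrial ribosomal RNA, 7.49% in this library, was not tested as a source of its place either.

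Clock genes differed between HFD Vehicle and HFD, with a clock phase score 2.47 higher in HFD Vehicle (exact two-sided permutation p = 0.1, the smallest possible for 3 against 3). Without HFD Vehicle 50 the difference was 1.81, against a range of 0.648 among the HFD libraries, which argues against that library alone as the cause. Without it Arntl and Npas2 together were at -0.92 on the log2 scale relative to HFD, and 9 of 9 genes of the opposite phase were higher, by 0.90 on average. These directions had been seen before the test was chosen and lend no support to any cause. Another time of day at tissue collection and an effect of injection or vehicle on the clock cannot be told apart, since collection times were not used here. HFD Vehicle 23, 50 and 55 had phase scores of 1.96, 4.09 and 2.25, that of HFD Vehicle 50 being the highest of the 12 libraries. HFD PCN libraries had 2.70 to 3.44, Chow libraries 0.847 to 3.06 and HFD libraries -0.132 to 0.516.

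Mesothelial markers were higher in HFD PCN than in HFD Vehicle, with a mean log2 level of 2.50 ± 0.44 against 0.62 ± 1.53 relative to Chow (SD, n = 3 each, exact two-sided permutation p = 0.2). The difference of 1.88 was smaller than the range of 2.43 within the untreated HFD libraries, so uneven amounts of mesothelium between samples may account for it. A range of single libraries is a loose measure for a difference of means and does not settle this. The HFD PCN libraries lay at 2.08 to 2.95, above all HFD (at most 1.17) and Chow (at most 0.910) libraries. HFD Vehicle 50 reached 2.27, and HFD Vehicle 23 and 55 lay at 0.336 and -0.748. On the same scale, leaving out any 1 library kept the median of the list, 2.12 with all libraries, at 1.39 or more, which argues against 1 library as its source. The log2 ratio of Slpi to the other markers differed by 0.458 (SD 0.655 with PCN and 1.13 with vehicle, exact two-sided permutation p = 0.5), a difference smaller than its spread. In the untreated HFD libraries this ratio was 1.35 to 3.35, above all 6 injected libraries (-1.01 to 1.23), so Slpi also varied apart from the other markers. Whether the amount of mesothelium accounts for the Slpi difference stays open. An effect of PCN on mesothelial cells stays open.

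Of the 10 splits of the 6 libraries of each comparison into 3 and 3, too few for a share under 0.05, the number with a result as large, the real one included, was as follows. For genes called in HFD against Chow it was 1 (9699 genes, highest other 0), in HFD PCN against HFD Vehicle 10 (0 genes, highest other 0) and in HFD Vehicle against HFD 10 (0 genes, highest other 0). For lists that passed camera it was 4 (16 lists, highest other 17), 7 (7 lists, highest other 16) and 5 (14 lists, highest other 18).

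The gene Gm26917, named after its values were seen, was at 3941 to 4971 CPM in the HFD libraries, 12460 to 61930 CPM in the Chow libraries and 9386 to 18170 CPM in the HFD PCN libraries. In HFD Vehicle 23, 50 and 55 it was at 13500, 43890 and 14810 CPM.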
